A study of Mus musculus with 30 samples.

How the data were processed

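The captured cells and the spheres were deposited in separate tables and were analysed apart. Per the labels' protocols, RNA was extracted with an RNeasy micro kit, turned into cDNA by Smart-seq2, a full-length method with polymerase chain reaction and no molecular identifiers, and made into libraries with Tn5 transposase. Counting error on such reads therefore covers reads and not molecules, and the protocol marks no strand, so overlapping and antisense genes cannot be separated. STAR 2.3, Salmon 1.6.0, DESeq2 1.34.0 and the builds mm10 and GRCm39 are named per the submitters' processing notes, without a role. The step that counted reads and the annotation are not given in the sources used here.

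The authors deposited normalized values for the 20 captured libraries whose unit is not given in the sources used here and which are not whole-number counts or TPM. The values behave as RPKM: low values of a gene are whole multiples of a step that depends on the gene and on the library. Whole reads were recovered in this way for 11773 of 14997 genes (78.5%), within 0.01 reads of a whole number, and they gave 1301926 to 4826888 reads per library. Tested on simulated data, this step recovered 97.2% of genes, and 99.7% of those exactly. The simulated values followed the rule for every gene, and fewer deposited genes could be resolved, so this exactness need not hold for them. The table joins the 4 ages by gene symbol and holds 15139 lines, of which 142 carry 1 of 11 repeated symbols and were left out. A further 21 symbols had been turned into dates and are kept but not named. A gene has values at an age only where the mean of that age's libraries is at least 1 unit, and 10721 genes had values at all 4 ages. Mitochondrially encoded genes were not analysed in captured libraries. The deposited counts of the 10 sphere libraries are whole numbers for 26005 genes, per the file headers with an Ensembl identifier and a symbol each, and may be Salmon estimates made whole by the authors. All columns were matched to samples by name, with 0 left out. Gene coordinates were taken from the GRCm38 annotation.

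Captured values were tested with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a trend in the prior variance, all 20 libraries in 1 fit with a mean per age, and contrasts of neighbouring ages, each over the genes listed at both ages. A fold change on this scale understates the change of low genes. The sphere counts were tested with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling and the default filter on low counts. The p-values were adjusted by Benjamini-Hochberg over all genes of a comparison with a threshold of 0.05. The design written before the data were examined asked for edgeR if the captured table held counts and limma if it held normalized values. It also asked for gene list tests on the same fit, but since missing ages cannot enter them, they used the libraries of the 2 ages compared.

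Before the data were examined, 22 lists were fixed: Sox9 and Nfi factors, midbrain floor plate identity, forebrain identity, proneural and early neuronal, dopamine neuron, cell cycle, motile cilia and ependymal, radial glia and neural stem, the Notch, hedgehog and Wnt pathways, astrocyte, oligodendrocyte lineage, mature neuron, microglia and macrophage, endothelial and mural, fibroblast and meninges, choroid plexus, erythroid, immediate early and heat shock, mitochondrially encoded, and antigen presentation and interferon. Some genes sit on more than 1 list. List members were matched through older symbols, and a synonym that is the symbol of another gene was not taken. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. With the estimated correlation no list call held between ages, and in the spheres all but those of fibroblasts and meninges and of mitochondrially encoded genes held. With fry every call held except those of motile cilia and ependymal genes for E13 against E11 and of mitochondrially encoded genes in the spheres. The named genes were fixed by rule: the 5 factors, then the 6 largest rises and 6 largest falls among genes that passed, had a mean of at least 5 units or 10 CPM (counts per library scaled to its size), did not overlap between groups and had no clone, predicted, mitochondrial or pseudogene name, and lastly up to 4 members of each list with the smallest p. Some genes that this rule selects are not reported here.

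The tests were run on simulated data with 200 changed genes per comparison. At a simulated fold of 4 they recovered 90.9% of changed genes for E13 against E11 (over 11567 genes) and for E18 against E13 (11797 genes), 93.9% for P70 against E18 (12353 genes) and 83.3% for MB against FB (12690 genes). At a fold of 2 the shares were 50.8%, 43.3%, 47.8% and 74.6%, and at 1.5 they were 8.96%, 5.97%, 7.46% and 41.8%, so a gene that did not pass may still differ by such folds. False calls numbered 6, 9, 1 and 8 in that order. In the deposited data far more genes passed than the 200 simulated, at 20.9%, 47.4%, 40.8% and 29.6% of those tested. The adjusted threshold is less strict when more genes change, so the simulated shares may understate recovery in the deposited data. Other differences may overstate it. Simulated errors were drawn separately for each gene, so departures shared by many genes of a library were absent. For captured libraries the folds were set on the log2(value + 1) scale, where they stand for larger changes in the values of low genes. The simulated shares and false calls may therefore look better than in the deposited data.

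Each library counted as 1 replicate, as the labels number them. Libraries of a group differed by more than read sampling (the lowest chi-square per degree of freedom was 6.97, over genes with at least 10 reads in the pair), which does not tell separate animals from repeated captures. The labels name no batch. Alternatives fixed beforehand were a pseudocount of 0.1, no filter with unlisted genes at 0, a filter at 5 units or 10 CPM, only the 2 ages in the fit, a replicate block, each library left out, an absolute log2 change of at least 1, and for spheres DESeq2 1.42.0, limma voom with quality weights and DESeq2 size factors. Alternatives added after the data were seen were unlisted genes at 1, median-ratio scaling, a weight per library, edgeR on recovered reads, leaving out E18 replicate 3 and P70 replicates 4 and 6, and leaving out mitochondrial genes. Tables were joined with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.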

Results

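Polyadenylated RNA was profiled in 30 mouse libraries of 2 kinds. Laser capture microdissection took floor plate cells of the midbrain at embryonic days 11, 13 and 18 (E11, E13, E18) and postnatal day 70 (P70). The cells were labelled through Lmx1aCreERT2, a tamoxifen-inducible recombinase driven by the floor plate gene Lmx1a. The floor plate is the ventral midline of the neural tube, where midbrain dopamine progenitors lie. There were 4 captured libraries at E11, 5 at E13, 5 at E18 and 6 at P70. The other 10 libraries came from spheres cultured from adult brain, 5 named MB and 5 named FB. The design text speaks of neurospheres from the lateral ventricle and ependymal spheres from the midbrain aqueduct, and the library names do not spell out MB and FB. The series title asks how Sox9 and the nuclear factor I (Nfi) transcription factors relate to the timing of neurogenesis and ependymal maturation. Levels in captured libraries are the deposited values, which behave like RPKM (called units here), and levels in spheres are CPM, counts scaled by library size. No label states that libraries of a group came from separate animals or cultures, or ties captures to animals. The p-values therefore measure only the spread between these samples and are too small where captures share an animal.

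Whole reads could be recovered behind the captured values for 11773 genes. They came to 3757315 to 4384409 reads per library at E11, 3216933 to 4826888 at E13, 3026000 to 4029730 at E18 and 1301926 to 3044743 at P70, so low genes were measured least precisely at P70. Sphere libraries held 6327198 to 9291311 counts. The captured table lists a gene at an age only where its mean there is at least 1 unit, with 12221 genes listed at E11, 12381 at E13, 13340 at E18 and 13291 at P70. Fold changes were tested for genes listed at both ages, and genes listed at 1 of the 2 ages are given as such.

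Sox9 encodes a transcription factor of neural stem cells and glia, and Nfia, Nfib, Nfic and Nfix encode the nuclear factor I proteins, which act in gliogenesis. On mouse build GRCm38, Sox9 lies on chromosome 11 from 112782224 to 112787760, Nfia on chromosome 4 from 97772734 to 98118874 and Nfib on the same chromosome from 82290173 to 82705750. Nfic lies on chromosome 10 from 81396186 to 81455635 and Nfix on chromosome 8 from 84699876 to 84800344. Sox9 measured 56.5 ± 15.7 units at E11 (SD, n = 4), 106 ± 37.9 at E13 (n = 5), 156 ± 62.7 at E18 (n = 5) and 416 ± 112 at P70 (n = 6). Nfia measured 5.51 ± 2.63, 49.4 ± 25.7, 133 ± 38.4 and 96.4 ± 27.6 units at these ages, and Nfib measured 4.18 ± 0.876, 46.5 ± 14.9, 37.2 ± 9.38 and 15.7 ± 4.99. Nfic measured 1.48 ± 0.186, 1.42 ± 0.104, 4.81 ± 1.65 and 24.3 ± 9.02 units. Nfix was not listed at E11 and measured 11.1 ± 3.55 at E13, 26.4 ± 14.1 at E18 and 62.6 ± 13.4 at P70.

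Between E11 and E13, Nfib rose by a log2 change of 3.15 (SE 0.26, limma adjusted p = 4.92e-08) and Nfia by 2.92 (SE 0.32, adjusted p = 1.58e-06). Sox9 rose by 0.85 (SE 0.29, limma adjusted p = 0.0385), while Nfic differed by -0.03 (SE 0.25, limma adjusted p = 0.952). Nfic lay near the listing floor of 1 unit, at 1.48 units at E11 and 1.42 at E13, where the log2(value + 1) scale understates change. With limma p-values adjusted over the list alone, Nfib, Nfia and Sox9 passed again (adjusted p = 2.16e-10, 1.52e-08 and 0.00969) and Nfic did not (adjusted p = 0.905). The Sox9 call was lost when E11 replicate 1, 2 or 3 or E13 replicate 1, 3 or 5 was left out, with log2 changes of 0.67, 0.90, 0.84, 0.79, 0.71 and 0.76 in that order. Its adjusted p over all settings tried ranged from 0.00159 to 0.154. Between E13 and E18, Nfia rose by 1.495 (SE 0.30, adjusted p = 0.000318), Nfic by 1.22 (SE 0.24, adjusted p = 0.000253) and Nfix by 1.05 (SE 0.32, adjusted p = 0.0111). Sox9 was 0.56 higher (SE 0.27, adjusted p = 0.0922) and Nfib differed by -0.29 (SE 0.25, adjusted p = 0.357), and neither passed. Without E13 replicate 3, Sox9 passed at 0.70, and its adjusted p over all settings ranged from 0.0458 to 0.285. List-alone adjustment gave 0.000150 for Nfia and for Nfic, 0.00675 for Nfix, 0.0614 for Sox9 and 0.253 for Nfib.

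From E18 to P70, Nfic rose by a log2 change of 2.10 (SE 0.23, limma adjusted p = 4.29e-07), Sox9 by 1.44 (SE 0.26, adjusted p = 0.000146) and Nfix by 1.36 (SE 0.31, adjusted p = 0.00170). Nfib fell by 1.22 (SE 0.24, adjusted p = 0.000351), and Nfia was lower by a difference of -0.47 that did not pass (SE 0.29, adjusted p = 0.201). Adjusted over the list alone, the same 4 genes passed, with p of 4.35e-08 for Nfic, 3.73e-05 for Sox9, 0.000400 for Nfix and 7.38e-05 for Nfib, against 0.117 for Nfia. The list as a group was not called by camera in any comparison where it could be tested (adjusted p = 0.177 for E18 against E13, 0.182 for P70 against E18 and 0.721 for MB against FB), and its members went both ways at P70 and in the spheres. By fry, which tests a list alone, it passed upward for E18 against E13 (adjusted p = 0.0130) and for P70 against E18 (adjusted p = 0.00891). It did not pass by fry for MB against FB (adjusted p = 0.195). In MB against FB spheres its median and mean were 0.06 and 0.10 while the test pointed down.

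**Figure D1:**
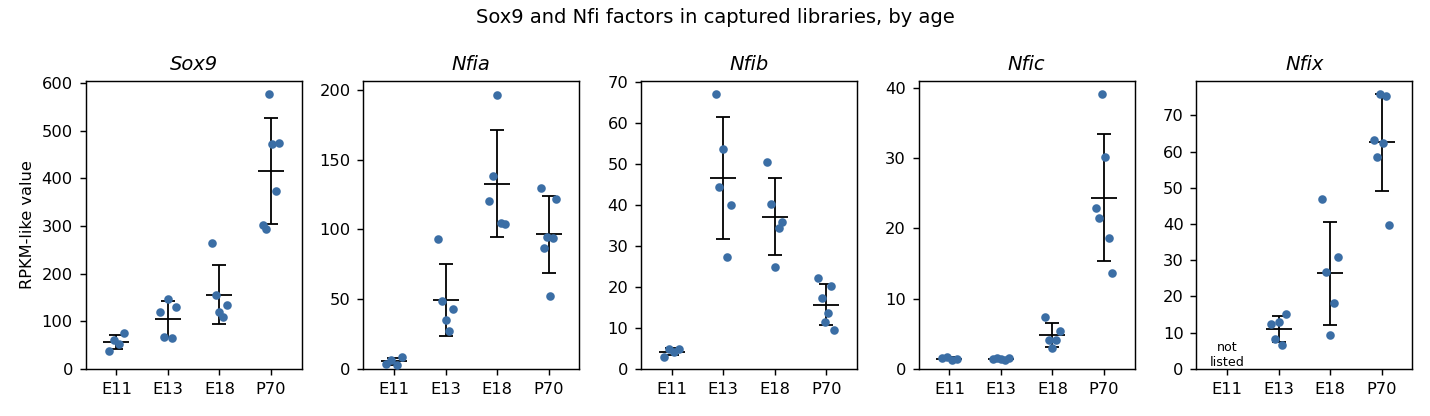
Level of Sox9, Nfia, Nfib, Nfic and Nfix (y axis, RPKM-like units from 0) in each captured library at 4 ages (x axis). Points are libraries, the wide tick is the mean and the bar 1 SD each way (n = 4, 5, 5 and 6). Sox9 lies between 293 and 578 units at P70 and between 37.3 and 74.8 at E11, and Nfix is not listed at E11.

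Between E11 and E13, 33 of 35 cell cycle genes fell, 10 of 17 astrocyte genes rose and 3 fell, and 11 of 18 mature neuron genes rose. None of these list calls held with an estimated correlation (adjusted p = 0.429 for each). Ndrg2, a gene of astrocytes and radial glia, rose from 2.25 ± 1.03 units at E11 (SD, n = 4) to 123 ± 37.5 at E13 (n = 5). Fabp7, a fatty acid binding protein of radial glia, rose from 355 ± 32.7 to 8467 ± 2523, and Mt3, a brain metallothionein, from 11.7 ± 3.37 to 478 ± 254. The median log2 change of the cell cycle genes was -1.83, and none rose. Crabp2, which binds retinoic acid inside cells, fell from 784 ± 294 to 52.4 ± 9.92 units.

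Among the largest rises by the fixed rule were those of Ndrg2 (log2 change 5.25, SE 0.22), Mt3 (5.09, SE 0.43), Fabp7 (4.53, SE 0.22), Aldh1l1 (4.37, SE 0.32) and Mmd2 (4.16, SE 0.32). Aldh1l1 is a folate enzyme used as an astrocyte marker. The 6 largest falls by that rule were those of Hbb-bh1 (-5.10, SE 0.96), Car14 (-4.15, SE 0.34), Crabp2 (-3.83, SE 0.45), Dkk2 (-3.64, SE 0.31), Dbx1 (-3.51, SE 0.61) and Gpc3 (-3.51, SE 0.38). Hbb-bh1 is an embryonic globin whose reads can be shared with other globin genes, Car14 a carbonic anhydrase, Dkk2 a secreted Wnt regulator, Dbx1 a homeobox factor of neural progenitors and Gpc3 a glypican.

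Top2a, the topoisomerase of dividing cells, fell by a log2 change of 2.26 (SE 0.23), and the replication helicase subunits Mcm5 by 2.52 (SE 0.30) and Mcm4 by 1.83 (SE 0.22). Adjusted over the list alone, all 35 cell cycle genes fell. For this list the camera adjusted p was 1.28e-19 (adjusted p = 0.429 with an estimated correlation). Of 18 mature neuron genes 11 rose and 0 fell, 15 rising when adjusted over the list alone, including the ubiquitin hydrolase Uchl1 (1.56, SE 0.20) and the synaptic vesicle gene Syn2 (1.342, SE 0.26). Their camera adjusted p was 2.33e-06 (adjusted p = 0.429 with an estimated correlation). Of 25 proneural and early neuronal genes 9 rose and 0 fell (13 and 1 over the list alone), among them neuronal tubulin Tubb3 (1.501, SE 0.27) and Stmn2 (2.13, SE 0.45), with a camera adjusted p of 0.000339 (adjusted p = 0.647 with an estimated correlation). Of 17 astrocyte genes 10 rose and 3 fell, unchanged over the list alone, Clu rising by 2.59 (SE 0.23), and 6 more were listed only at E13 and 2 only at E11 (camera adjusted p = 0.000384, and adjusted p = 0.429 with an estimated correlation).

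Genes of radial glia and neural stem cells rose in 7 of 24 and fell in 1, also over the list alone, with the smallest p after Fabp7 in Ddah1 (1.96, SE 0.22) and the glutamate transporter Slc1a3 (2.80, SE 0.32). By camera the adjusted p was 0.0344 (adjusted p = 0.661 with an estimated correlation). Of 27 motile cilia and ependymal genes 8 rose and 1 fell, the same over the list alone, with Mia at 2.11 (SE 0.20) and Dynlrb2, a dynein light chain, at 3.06 (SE 0.37), and 5 more were listed only at E13 and 1 only at E11. Their camera adjusted p was 0.0309 (adjusted p = 0.661 with an estimated correlation). Nr4a2, a transcription factor of dopamine neurons, rose by 2.57 (SE 0.38), and 2 of the 8 dopamine neuron genes tested rose, with 6 listed only at E13 and 1 only at E11 (camera adjusted p = 0.147). Among 21 midbrain floor plate genes 3 rose and 1 fell, or 3 and 2 over the list alone, En1 rising by 2.77 (SE 0.51) and the signalling factor Shh falling by a log2 value of -1.10 (SE 0.28, camera adjusted p = 0.216).

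Markers of other cell types moved over the same interval. Of 16 microglia and macrophage genes 10 rose and 0 fell (10 and 1 over the list alone), with complement C1qa at 2.002 (SE 0.34) and the protease Ctss at 2.51 (SE 0.43). Their camera adjusted p was 0.000148 (adjusted p = 0.358 with an estimated correlation). Of 13 fibroblast and meninges genes 9 fell and 0 rose (10 over the list alone), with vitronectin Vtn at -3.10 (SE 0.39) and fibronectin Fn1 at -1.97 (SE 0.26), and the camera adjusted p was 2.67e-05 (adjusted p = 0.429 with an estimated correlation). The other lists were not called. Rises and falls were 1 and 1 of 22 for the Notch pathway (camera adjusted p = 0.853), 0 and 2 of 7 for the hedgehog pathway (0.211), 4 and 5 of 27 for the Wnt pathway (0.571) and 2 and 1 of 6 for the oligodendrocyte lineage (0.961). They were 0 and 3 of 15 for endothelial and mural genes (0.425), 0 and 2 of 6 for erythroid genes (0.0665), 0 and 0 of 14 for immediate early and heat shock genes (0.527) and 1 and 1 of 7 for antigen presentation and interferon genes (0.724). Choroid plexus genes rose in 3 and fell in 1 of 8 (camera adjusted p = 0.456), with a median of -0.15, a mean of 0.57 and a test that pointed up. Neither of the 2 forebrain identity genes tested passed. Adjusted over the list alone, rises and falls became 0 and 1 for the Notch pathway, 1 and 4 for the hedgehog pathway, 4 and 7 for the Wnt pathway, 2 and 2 for the oligodendrocyte lineage, 2 and 6 for endothelial and mural genes and 1 and 3 for erythroid genes, with the other lists of this paragraph unchanged.

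Over all 11567 genes tested by limma, 1092 were higher and 1329 lower at E13 than at E11 at an adjusted p under 0.05, and 814 genes were listed only at E13 and 654 only at E11. The count of 2421 changed with the fit: fitting only these 2 ages gave 3811 and a weight per library gave 4873.

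Between E13 and E18 every motile cilia gene that could be tested rose, and 31 of 32 cell cycle and 18 of 21 proneural genes fell. These list calls did not hold with an estimated correlation (adjusted p = 0.0563, 0.263 and 0.0563). All 32 motile cilia and ependymal genes tested rose, with a median log2 change of 4.05, and 31 more were listed at E18 and not at E13. Mia, a secreted protein placed on the ependymal list, rose from 19.6 ± 4.18 units at E13 (SD, n = 5) to 2920 ± 526 at E18 (n = 5), and Dynlrb2 from 19.8 ± 8.78 to 1573 ± 274. Tmem212, the highest of the ciliary genes listed only at E18 and picked out after its value was seen, measured 2150 ± 533 units there. The proneural factor Neurog2, picked out in the same way, measured 209 ± 80.5 units at E13 and was not listed at E18.

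The 6 largest rises by the fixed rule were those of Mia (log2 change 7.16, SE 0.19), the opioid precursor Pdyn (7.003, SE 0.47), Ppp1r32 (6.67, SE 0.18), the troponin Tnnt3 (6.53, SE 0.27), Dynlrb2 (6.35, SE 0.35) and Sparcl1 (6.33, SE 0.24), a matrix protein made by astrocytes. The 6 largest falls by that rule were those of the embryonic globin Hbb-y (-11.21, SE 0.96), the Notch-modifying enzyme Mfng (-5.85, SE 0.46), the ribosomal protein gene Rps18 (-5.78, SE 1.27), the cell cycle inhibitor Cdkn1c (-4.76, SE 0.27), the ubiquitin enzyme Ube2c of mitosis (-4.60, SE 0.46) and Hepacam2 (-4.50, SE 0.37). Rps18 is uncertain, since it has near-identical copies in the genome that reads can be split among. It ranged from 14.9 to 464 units within E13.

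Among ciliary genes Rsph1, of the radial spoke, rose by 5.70 (SE 0.21), Wdr16 by 6.04 (SE 0.25) and Pifo by 6.30 (SE 0.27). By camera this list had an adjusted p of 1.14e-25 (adjusted p = 0.0563 with an estimated correlation), and all 32 also rose when adjusted over the list alone. Of 32 cell cycle genes 31 fell, or 32 over the list alone, with Mcm2 at -3.18 (SE 0.26) and cyclin Ccna2 at -2.97 (SE 0.26), and 3 more were listed at E13 and not at E18. Their camera adjusted p was 7.07e-14 (adjusted p = 0.263 with an estimated correlation). Of 21 proneural and early neuronal genes 18 fell and 0 rose, also over the list alone, with Btg2, an antiproliferative gene of neurogenic divisions, at -3.35 (SE 0.26) and Hes6 at -3.28 (SE 0.27). A further 5 were listed only at E13, and the camera adjusted p was 5.64e-09 (adjusted p = 0.0563 with an estimated correlation). Astrocyte genes rose in 19 of 23 and fell in 1, the same over the list alone, with Atp1b2 at 4.70 (SE 0.20) and the apolipoprotein Apoe at 3.88 (SE 0.18), and their camera adjusted p was 6.55e-09 (adjusted p = 0.226 with an estimated correlation).

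Midbrain floor plate genes fell in 11 of 20 and rose in 1, also over the list alone. Otx2, a homeobox gene of the midbrain, fell from 186 ± 49.8 to 38.1 ± 9.57 units (log2 change -2.25, SE 0.22), Foxa2 from 111 ± 12.7 to 33.2 ± 5.45 (-1.72, SE 0.21), and the axon guidance gene Ntn1 rose from 105 ± 27.1 to 317 ± 55.5 units. The camera adjusted p was 0.0141 (adjusted p = 0.508 with an estimated correlation). Of 13 dopamine neuron genes 3 rose and 4 fell (3 and 5 over the list alone), Nr4a2 falling by a log2 change of 3.35 (SE 0.36) and Calb1, a calcium-binding protein, rising by 3.01 (SE 0.42), with a camera adjusted p of 0.968. Radial glia and neural stem genes split into 10 that rose and 9 that fell of 25 (10 and 11 over the list alone), with the differentiation inhibitor Id3 at -3.85 (SE 0.21) and Dbi at 3.15 (SE 0.19), and the camera adjusted p was 0.886. Notch pathway genes rose in 4 and fell in 7 of 20 (camera adjusted p = 0.177), Dtx1 rising by 3.01 (SE 0.28).

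Neuronal and vascular markers also moved. Mature neuron genes rose in 10 of 21 and fell in 1 (11 and 1 over the list alone), Syn2 rising by 2.27 (SE 0.24), with a camera adjusted p of 0.00118 (adjusted p = 0.590 with an estimated correlation). Endothelial and mural genes fell in 9 of 16 and rose in 1 (10 fell over the list alone), Pecam1 at -1.11 (SE 0.25), with a camera adjusted p of 0.0398 (adjusted p = 0.226 with an estimated correlation). Both erythroid genes tested fell, though the call for Alas2 was lost in 8 of the fits with 1 library left out, and 4 more, all globin or red cell genes, were listed at E13 and not at E18. The other lists were not called. Rises and falls were 1 and 2 of 8 for the hedgehog pathway (camera adjusted p = 0.997), 4 and 9 of 21 for the Wnt pathway (0.313), 3 and 1 of 7 for the oligodendrocyte lineage (0.301) and 3 and 1 of 18 for microglia and macrophages (0.313). They were 2 and 4 of 10 for fibroblasts and meninges (0.551), 2 and 5 of 8 for choroid plexus (0.372) and 2 and 1 of 9 for antigen presentation and interferon (0.507). Immediate early and heat shock genes rose in 3 and fell in 2 of 14 (0.905), with a median of 0.13, a mean of -0.10 and a test that pointed up, and 1 of the 3 forebrain identity genes tested rose (median -0.49, mean 0.18). Adjusted over the list alone, rises and falls became 5 and 9 for the Notch pathway, 5 and 9 for the Wnt pathway, 2 and 1 for microglia and macrophages and 1 and 1 for forebrain identity, with the other lists of this paragraph unchanged.

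Over all 11797 genes tested by limma, 2644 were higher and 2948 lower at E18, and 1543 genes were listed only at E18 and 584 only at E13. Which side was larger depended on the setting: median-ratio scaling gave 2816 higher and 2681 lower, and edgeR on recovered reads gave 2513 and 2230. Without E18 replicate 3 and P70 replicates 4 and 6, left out by a choice made after the data were seen, 6035 genes passed in place of 5592, and all 32 ciliary genes rose.

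**Figure D2:**
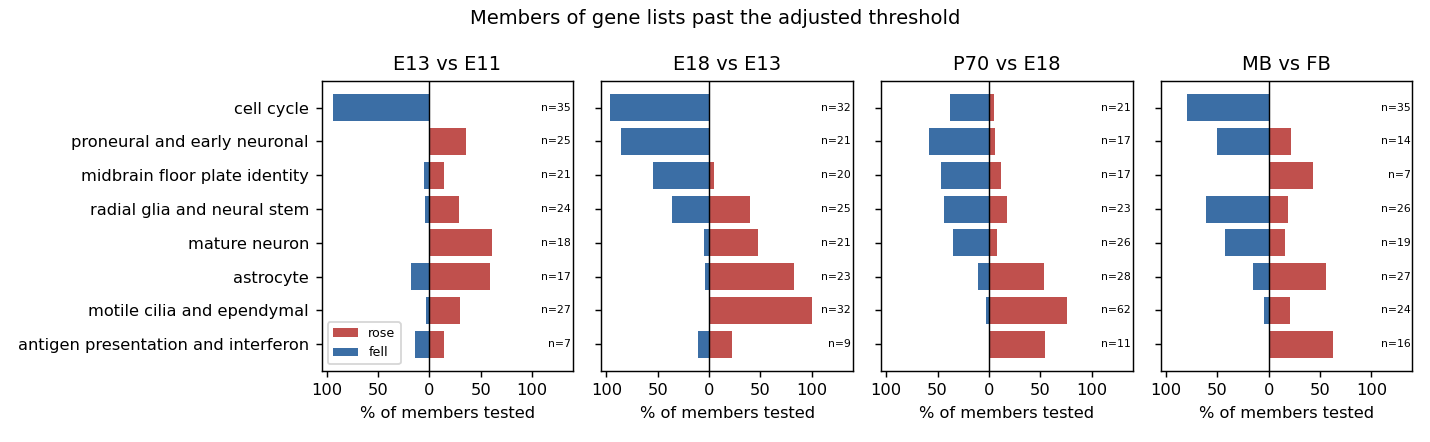
Share of tested members (x axis, percent) of 8 gene lists that rose (red, right of 0) or fell (blue, left of 0) at an adjusted p under 0.05 in the 4 comparisons, with the number of members tested at the right edge. Among the cilia genes 32 of 32 rose at E18 and 47 of 62 at P70.

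Between E18 and P70, 47 of 62 motile cilia and 15 of 28 astrocyte genes rose and 10 of 17 proneural genes fell. They were not called as lists with an estimated correlation (adjusted p = 0.0673, 0.194 and 0.0770). Sntn, of the ciliary tip, rose from 2.61 ± 1.83 units at E18 (SD, n = 5) to 171 ± 81.9 at P70 (n = 6), and Gfap, the intermediate filament of astrocytes, from 1.65 ± 2.24 to 111 ± 52.4. The motile cilia and ependymal genes had a median log2 change of 1.17, and 2 of them fell. Spp1, osteopontin, fell from 407 ± 227 to 1.06 ± 1.48 units. Its lowest E18 library stood at 15.4 units and the next at 405. Prom1, a membrane protein of progenitor and ependymal cells, fell from 596 ± 198 to 25.5 ± 9.95. The median of all genes was -0.14 in this comparison, and 0.01 with median-ratio scaling chosen after the data were seen, so log2 changes here stand about that far below those of the other scaling.

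The 6 largest rises by the fixed rule were those of Stoml3 (log2 change 6.01, SE 0.41), a stomatin of ciliated cells, Hist1h4h (5.89, SE 0.45), Gfap (5.58, SE 0.41), Sntn (5.57, SE 0.36), Ptgds (5.32, SE 0.28), the prostaglandin D synthase of meninges and glia, and Unc5cl (5.30, SE 0.30). Hist1h4h belongs to a family of near-identical histone genes and its reads may be shared, so its level is uncertain. The 6 largest falls by that rule were those of Spp1 (-7.24, SE 0.70), the ephrin Efnb3 of the ventral midline (-5.83, SE 0.30), the microfibril gene Mfap2 (-5.63, SE 0.50), Dpysl3 of growing axons (-5.01, SE 0.29), Prom1 (-4.51, SE 0.25) and the chemokine receptor Ackr1 (-4.36, SE 0.29).

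On the motile cilia and ependymal list Rarres2 (4.56, SE 0.36), Ccdc153 (5.09, SE 0.33) and Tctex1d4 (4.18, SE 0.28) followed Sntn. Of this list 51 genes rose and 2 fell when adjusted over the list alone. Mcidas, a regulator of centriole amplification, was listed at E18 (6.50 ± 5.23 units) and not at P70. By camera the list had an adjusted p of 1.55e-21 (adjusted p = 0.0673 with an estimated correlation). Mature neuron genes, measured in the same captures, rose in 2 and fell in 9 of 26 (10 over the list alone, camera adjusted p = 0.0739), Syn2 falling by 1.31 (SE 0.24) and Camk2a rising by 2.25 (SE 0.41). Astrocyte genes rose in 15 of 28 and fell in 3 (18 and 3 over the list alone), with Ntsr2 at 3.80 (SE 0.25) and the calcium-binding protein S100b at 4.46 (SE 0.28). Their camera adjusted p was 5.66e-07 (adjusted p = 0.194 with an estimated correlation). Oligodendrocyte genes rose in 8 of 12 and fell in 1 (8 and 3 over the list alone), with transferrin Trf at 3.28 (SE 0.24) and myelin basic protein Mbp at 5.07 (SE 0.38). A further 9 were listed only at P70 and 2 only at E18, and the camera adjusted p was 0.00122 (adjusted p = 0.358 with an estimated correlation).

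Antigen presentation and interferon genes rose in 6 of 11 and fell in 0, the same over the list alone, with B2m, the light chain of class I molecules, at 1.62 (SE 0.21) and Irf1 at 2.06 (SE 0.24), and 9 more were listed only at P70 and 1 only at E18. The camera adjusted p was 0.000235 (adjusted p = 0.0673 with an estimated correlation). Immediate early and heat shock genes, which can also rise during tissue handling, rose in 8 of 19 and fell in 1 (10 and 1 over the list alone), with Zfp36 at 2.66 (SE 0.21) and Atf3 at 3.24 (SE 0.28), and their camera adjusted p was 0.000352 (adjusted p = 0.0673 with an estimated correlation). Proneural and early neuronal genes fell in 10 of 17 and rose in 1 (11 fell over the list alone), with Tubb3 at -2.94 (SE 0.25) and Sox11 at -2.73 (SE 0.24). Their camera adjusted p was 0.00122 (adjusted p = 0.0770 with an estimated correlation). Floor plate genes fell in 8 of 17 and rose in 2, also over the list alone, Ntn1 at -3.70 (SE 0.20), the repellent Slit2 at -2.86 (SE 0.17) and Lmx1a at -2.12 (SE 0.26), with a camera adjusted p of 0.0121 (adjusted p = 0.401 with an estimated correlation). Wnt pathway genes fell in 7 of 17 and rose in 2 (8 fell over the list alone), the secreted inhibitor Sfrp1 at -2.01 (SE 0.30), and their camera adjusted p was 0.0483 (adjusted p = 0.380 with an estimated correlation).

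Cell cycle genes fell in 8 of 21 and rose in 1, with 11 more listed at E18 and not at P70 (camera adjusted p = 0.0858), Cdca8 falling by 2.43 (SE 0.36). Radial glia and neural stem genes fell in 10 and rose in 4 of 23 (camera adjusted p = 0.0903), Fabp7 falling by 3.61 (SE 0.20). Dopamine neuron genes rose in 3 and fell in 3 of 15 (camera adjusted p = 0.902), and Th, tyrosine hydroxylase, ranged from 8.47 to 337 units over the P70 libraries. Among the remaining lists, rises and falls were 0 and 6 of 20 for the Notch pathway (camera adjusted p = 0.182), 6 and 3 of 18 for microglia and macrophages (0.102), 2 and 1 of 12 for endothelial and mural genes (0.368) and 3 and 2 of 10 for choroid plexus (0.373). Fibroblast and meninges genes rose in 3 and fell in 3 of 9 (0.937), with a median of -0.46, a mean of 0.04 and a test that pointed up. No hedgehog pathway gene of 7 passed (0.856), with a median of -0.14, a mean of -0.04 and a test that pointed up. Both forebrain identity genes tested fell, and 1 of 2 erythroid genes, Alas2, rose, but the calls for Alas2 and for the forebrain gene Pax6 were lost in 6 and 4 of the fits with 1 library left out. When adjusted over the list alone, 5 Notch pathway genes fell and 4 choroid plexus genes rose, with the other lists of this paragraph unchanged.

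Over all 12353 genes tested by limma, 2082 were higher and 2960 lower at P70 (41.3% higher), against 2610 higher and 2172 lower with median-ratio scaling (54.6% higher), and 938 genes were listed only at P70 and 987 only at E18. The edgeR test on recovered reads, over 9729 genes, called 1551 higher and 1329 lower (53.9% higher). Without E18 replicate 3 and P70 replicates 4 and 6, 4797 genes passed in place of 5042, and 45 ciliary genes rose.

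Among the cultured spheres, 15 of 27 astrocyte genes were higher in MB and 4 lower. Of the 21 midbrain floor plate genes found in the sphere counts only 7 passed the filter on low counts, and 3 of these 7 were higher. In turn, 8 of 10 forebrain and 28 of 35 cell cycle genes were lower. Six3, a transcription factor of the forebrain, was lower in MB by a log2 difference of -6.91 (SE 0.51, n = 5 and 5). Otx2, on both the midbrain floor plate and the choroid plexus lists, measured 16.4 ± 0.845 CPM in MB (SD, n = 5) and 2.42 ± 1.498 in FB (n = 5). Agt, angiotensinogen, made by astrocytes, measured 208 ± 24.4 in MB and 8.56 ± 3.18 in FB. Sox9 was lower in MB, at 194 ± 18.5 against 294 ± 14.7 CPM.

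The 5 factors of the series title did not move together. Sox9 differed by a log2 value of -0.60 (SE 0.07, edgeR adjusted p = 1.52e-06) and Nfib, at 217 ± 5.54 in MB and 272 ± 22.9 in FB, by -0.33 (SE 0.06, adjusted p = 0.000539). Nfic was higher in MB, at 21.6 ± 1.81 against 10.9 ± 2.12 (0.97, SE 0.19, adjusted p = 0.000570), and so was Nfix, at 125 ± 16.03 against 95.0 ± 5.81 (0.40, SE 0.09, adjusted p = 0.00234). Nfia, at 296 ± 44.7 and 284 ± 34.9, did not pass (0.06, SE 0.10, adjusted p = 0.686). Adjusted over the list alone, p was 2.59e-07 for Sox9, 0.000101 for Nfib and for Nfic, 0.000420 for Nfix and 0.538 for Nfia.

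**Figure D3:**
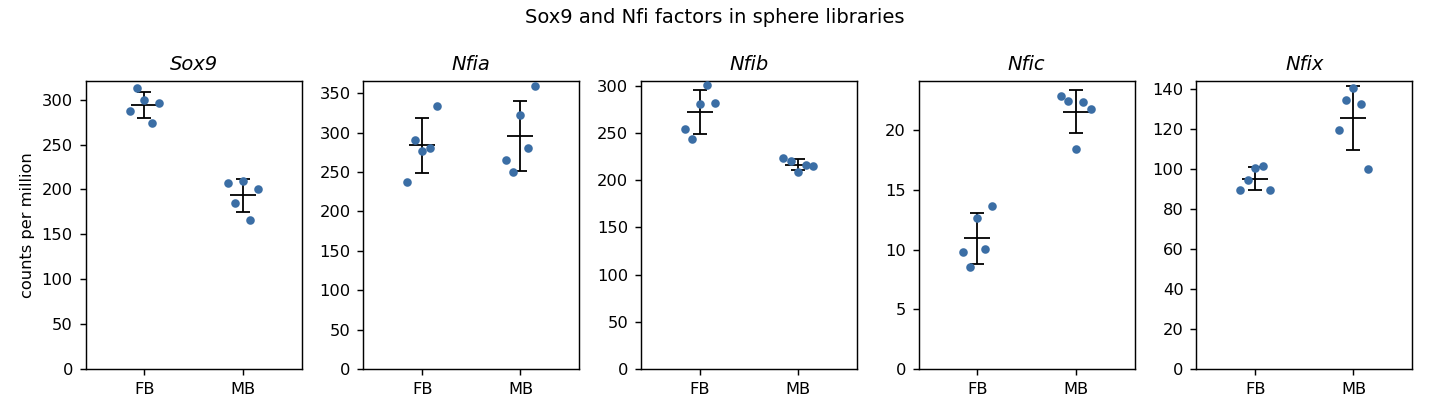
Level of Sox9, Nfia, Nfib, Nfic and Nfix (y axis, CPM from 0) in FB and MB sphere libraries (x axis). Points are libraries, the wide tick is the mean and the bar 1 SD each way (n = 5 each). Sox9 lies between 166 and 210 in MB and between 274 and 313 in FB.

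By the fixed rule, which asks for a mean of at least 10 CPM, the 6 genes most raised in MB were Cnpy1 (log2 difference 6.46, SE 0.40), a gene of the midbrain-hindbrain boundary, Agt (4.58, SE 0.16), the retinaldehyde dehydrogenase Aldh1a1 (4.23, SE 0.31), Pdlim3 (3.98, SE 0.35), the extracellular superoxide dismutase Sod3 (3.75, SE 0.17) and the glycogen phosphorylase Pygm (3.72, SE 0.14). The 6 most lowered by that rule were transthyretin Ttr (-9.01, SE 0.37), thrombomodulin Thbd (-6.30, SE 0.44), Rgs16 (-3.59, SE 0.21), the hedgehog co-receptor Cdon (-3.13, SE 0.54), Fndc3c1 (-3.09, SE 0.11) and thrombospondin Thbs2 (-2.99, SE 0.19). Ttr measured 0.0566 ± 0.0776 CPM in MB and 36.6 ± 3.27 in FB, so its fold rests on very few MB counts. Thbd and Cdon were also low in MB, at 0.472 ± 0.561 and 2.14 ± 2.46 CPM. The log2 difference of Cdon was -4.07 without MB replicate 3 and -2.81 without MB replicate 5.

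Of 27 astrocyte genes 15 were higher and 4 lower in MB, the same over the list alone, with Apoe at 1.69 (SE 0.04) and Clu at 1.89 (SE 0.09), and the camera adjusted p was 1.82e-13 (adjusted p = 0.000471 with an estimated correlation). Of 10 forebrain identity genes 8 were lower and 0 higher (8 and 1 over the list alone), with a median of -3.20 and Meis2 at -2.33 (SE 0.16), and the camera adjusted p was 4.37e-09 (adjusted p = 0.00595 with an estimated correlation). Of 7 midbrain floor plate genes 3 were higher and 0 lower, also over the list alone, Spon1 at 2.36 (SE 0.08), Otx2 at 2.75 (SE 0.34) and Ntn1 at 0.48 (SE 0.12). Their camera adjusted p was 8.18e-06 (adjusted p = 0.00595 with an estimated correlation). The sphere counts held 21 genes of the floor plate list and 21 of the forebrain list, so most floor plate genes were too low to test. Of 35 cell cycle genes 28 were lower and 0 higher (29 over the list alone) by a median of -0.38, cyclins Ccnd1 at -0.38 (SE 0.04) and Ccna2 at -0.68 (SE 0.07), with a camera adjusted p of 3.83e-09 (adjusted p = 0.00595 with an estimated correlation).

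Radial glia and neural stem genes were lower in 16 and higher in 5 of 26 (16 and 6 over the list alone), with the matrix protein Tnc at -1.64 (SE 0.06) and the Notch target Hes5 at -2.20 (SE 0.10), and the camera adjusted p was 5.89e-08 (adjusted p = 0.00214 with an estimated correlation). Notch pathway genes were lower in 11 and higher in 1 of 19, also over the list alone, the ligand Dll1 at -1.46 (SE 0.09), with a camera adjusted p of 8.80e-06 (adjusted p = 0.00595 with an estimated correlation). Proneural and early neuronal genes were lower in 7 and higher in 3 of 14 (9 and 4 over the list alone), Btg2 at -1.34 (SE 0.08), with a camera adjusted p of 1.44e-05 (adjusted p = 0.00595 with an estimated correlation). Immediate early and heat shock genes were lower in 12 and higher in 2 of 23 (13 and 2 over the list alone), Jun at -1.12 (SE 0.07), with a camera adjusted p of 1.95e-05 (adjusted p = 0.0121 with an estimated correlation). Antigen presentation and interferon genes were higher in 10 and lower in 0 of 16 (11 over the list alone), the peptide transporter Tap2 at 1.96 (SE 0.16), with a camera adjusted p of 0.000442 (adjusted p = 0.0121 with an estimated correlation). Fibroblast and meninges genes were higher in 4 and lower in 2 of 13, the same over the list alone, Ptgds at 1.30 (SE 0.07), with a camera adjusted p of 0.00584 (adjusted p = 0.133 with an estimated correlation).

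Of 13 mitochondrially encoded genes 7 were lower and 0 higher (9 over the list alone), with mt-Atp6 at -0.999 (SE 0.23) and a camera adjusted p of 0.0249 (adjusted p = 0.557 with an estimated correlation). Motile cilia and ependymal genes were higher in 5 and lower in 1 of 24, the ciliogenesis factor Foxj1 at 0.77 (SE 0.19) and Rarres2 at 1.55 (SE 0.40), and the list was not called (camera adjusted p = 0.337). Choroid plexus genes went apart, Ttr against Otx2 and Sostdc1 (3.21, SE 0.53), with 4 higher and 2 lower of 10 (camera adjusted p = 0.793). Of 4 dopamine neuron genes 2 were higher, too few for a list test. Higher and lower genes were 5 and 9 of 20 for the oligodendrocyte lineage (camera adjusted p = 0.149), Mbp at -2.61 (SE 0.21), 3 and 8 of 19 for mature neurons (0.426), 2 and 0 of 7 for microglia and macrophages (0.0929) and 4 and 2 of 10 for endothelial and mural genes (0.403). Hedgehog pathway genes were higher in 2 and lower in 2 of 9 (0.143), with a median of 0.15, a mean of -0.31 and a test that pointed down. Wnt pathway genes were higher in 5 and lower in 7 of 25 (0.702), with a median of -0.06, a mean of 0.16 and a test that pointed up. When adjusted over the list alone, 4 microglia, 4 mature neuron and 5 choroid plexus genes were higher and 3 endothelial and 3 hedgehog pathway genes lower, with the other lists named since motile cilia unchanged. No erythroid gene passed the filter.

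Over all 12886 genes tested by edgeR, 1975 were higher and 1843 lower in MB at an adjusted p under 0.05. Samples of the 2 sets could not be matched by animal or culture, and the sets differ in both region and culture name, so region and culture cannot be told apart.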

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

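The test of library scaling was chosen only after its result was seen, and Prl, Gh and Cga were examined after their values had been seen. The tests with the neuron covariate, thinned reads, splits and other pituitary markers were fixed before their results were seen. The correlations of neuron and cilia scores and the search for libraries far from the others were not among the tests fixed beforehand. Each of 143 combinations of a named gene or library measure with a group was tested for a library far from the others, and 3 more after the values were seen. Of the 143, 8 stood out, about the 1 in 20 that chance alone would give, and the 3 others were picked because they stood out.

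In P70 replicate 4 the pituitary hormone genes Prl and Gh measured 6004 and 7232 units, against at most 0.539 and 1.33 in the other P70 libraries, and Cga measured 137.85 against 0. A candidate source is pituitary tissue carried into that capture. Pomc, the other abundant pituitary gene, was also highest there at 76.8 units against 20.6 to 45.4, but it had been seen beforehand. Of the pituitary markers set down for the test only 2 were listed at P70, and 0 of these 2 were highest in that library, Lhb because it lay at 132 to 380 units in every P70 library and Tshb because it stayed at or under 6.41. These 2 are too few and too near their floor or baseline to decide, so the explanation stays open, and no biological explanation was tested.

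Motile cilia genes were higher at P70 than at E18 by a median log2 change of 1.17. Fewer neurons in the P70 captures may contribute. With the mature neuron score as a covariate the median stayed at 0.91, and 41 of 62 genes rose (49 without the covariate in the same fit of these 2 ages). The score, a mean of log2 marker levels, thus did not account for the whole rise. It is not a count of neurons, and of its 26 genes 2 rose and 9 fell with age. This test therefore cannot decide how much of the rise fewer neurons explain. Shallower P70 libraries were argued against, since reads thinned to 1292348 per library gave 1.16 against 1.19 unthinned over 55 members. Over the 11 E18 and P70 libraries, centred within each age, the neuron and cilia scores ran opposite (Pearson r -0.716, permutation p = 0.00088; Spearman rho -0.818, permutation p = 0.00277; r -0.784 without the 2 libraries farthest from the median), and within the 6 P70 libraries r was -0.903 (exact permutation p = 0.0264) and rho -0.657 (exact permutation p = 0.175). Within E18 r was -0.935. The cilia score ranged from 5.484 to 6.256 over the E18 libraries and only from 6.998 to 7.165 over those of P70. Capture composition thus stays open as a source of spread between libraries, and maturation with age as an untested hypothesis.

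More genes were lower than higher at P70 than at E18, 41.3% of the 5042 that passed being higher. Whether scaling of each library to its total accounts for this stays open: with median-ratio scaling 54.6% were higher, but that scaling centres the genes, so its outcome was fixed and decides nothing. Shallower P70 libraries were argued against, since thinned reads gave 43.7% against 45.5% unthinned in the same genes. Which scaling is right stays open, because neither holds an outside standard.

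Chance assignment of libraries to groups was tested on 100 splits per comparison, the real one included. Only 1 of the 100 splits, the real one, gave as many changed genes in each comparison, which argues against chance assignment of these libraries and says nothing of animals or cultures that libraries may share. The highest of the other splits gave 1178 genes against 2421 for E13 and E11, 1048 against 5592 for E18 and E13, 3514 against 5042 for P70 and E18, and 0 against 3818 for MB and FB.

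Other libraries stood apart for single values. Nfic was lowest in MB replicate 3, at 18.4 CPM against 21.8 to 22.9 in the others. Sparcl1 measured 40.8 units in E13 replicate 1 against 16.1 to 22.8. E18 replicate 1 was highest for Stoml3, at 6.49 against 0 to 0.821, and for Gfap, at 5.60 against 0.224 to 1.18. Thbd measured 49.3 in FB replicate 5 against 31.5 to 35.5, and Thbs2 11.8 in MB replicate 2 against 5.47 to 7.15. Genes at 0 numbered 94 in E11 replicate 1 against 115 to 118, and 281 in E18 replicate 3 against 146 to 164.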

How the results depend on the processing

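Median-ratio scaling, unlisted genes at 1, library weights, edgeR on recovered reads, leaving out mitochondrial genes and the libraries left out together were chosen after the data were seen, and the other settings before. Counts of changed genes stayed within 1.5 times in 72 of 80 settings, and list tests kept direction and side of the threshold in 105 of 154. The 5 factors did so in 338 of 349 and named genes in 5989 of 6153 (86 lost and 76 gained the call, 2 changed sign). Under another scaling, list medians moved by less than a member gene's spread between libraries in 84 of 84. That limit is wide beside the shift scaling gave the median of all genes (-0.14 against 0.01 at P70), so this says little. Where the cause of a change is not given, the cause was not tested.

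Requiring an absolute log2 change of at least 1 left 1273, 3221, 2624 and 1048 genes for E13 against E11, E18 against E13, P70 against E18 and MB against FB, fewer by construction. For E13 against E11, unlisted genes at 0 gave 4008, only the 2 ages 3811 and library weights 4873. For P70 against E18, recovered reads gave 2880, with the test, the scaling and the genes all changed at once. With an estimated correlation 0, 0 and 0 of the lists fixed beforehand passed in the 3 age comparisons, against 8, 7 and 8. By fry, which tests a list alone, direction was opposite to camera without passing for the Notch pathway at E13 (adjusted p = 0.836), immediate early genes at E18 (adjusted p = 0.243), and dopamine neuron (adjusted p = 0.660) and hedgehog genes at P70 (adjusted p = 0.958), from limma. Fry kept the camera calls except motile cilia for E13 against E11 (fry adjusted p = 0.193) and mitochondrially encoded genes in the spheres (fry adjusted p = 0.142). It also passed lists that camera did not call, such as the Notch pathway at E18 (fry adjusted p = 4.85e-05) and at P70 (fry adjusted p = 0.000254).

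Leaving out each library in turn gave 1773 to 2238, 5045 to 5405, 4395 to 5186 and 3422 to 3632 changed genes. Sox9 ranged from 0.67 to 1.00 for E13 against E11, losing the call in 6 of these fits, and from 0.36 to 0.70 for E18 against E13, passing without E13 replicate 3, as it did on recovered reads (0.69). Values that did not pass changed sign for Nfic at E13 (-0.0682 to 0.0166, positive without E11 replicate 2), Nfia in spheres (-0.0209 to 0.130, negative without MB replicate 5) and Hbb-y at P70 (-0.36 to 1.18, negative without P70 replicate 3, and -0.35 with library weights).

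Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated above 0.1 in 0 of 4, 1 of 5, 0 of 5 and 0 of 5 pairs. Of these pairs only 0, 1, 2 and 1 had a later or MB library that correlated best with its own number. With the replicate block 2622, 5791, 4892 and 3650 genes passed, and Sox9 for E13 against E11 was 0.84 (adjusted p = 0.0654). Depth limited P70 most, at 1301926 to 3044743 recovered reads per library. Genes at 0 did not follow depth there. P70 replicate 6 had 1070 of them at 2756659 reads, and replicate 4 had 450 at 1301926.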

Other observations

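All lists in this part were chosen after their genes had been seen to move, so their tests describe these libraries and are not independent evidence.

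Sterol synthesis genes, 21 of which were tested in each comparison, fell in 18 and rose in 1 between E18 and P70, with a median log2 change of -1.50. Hmgcs1, an early enzyme of the pathway, fell by 3.29 (SE 0.20) and Cyp51, a later one, by 2.95 (SE 0.19), while Ebp rose by 1.07 (SE 0.17). The camera adjusted p was 1.83e-09 (adjusted p = 0.00959 with an estimated correlation). Between E13 and E18 15 of them rose and 0 fell (camera adjusted p = 2.92e-05, and adjusted p = 0.119 with an estimated correlation), and between E11 and E13 8 fell and 0 rose (camera adjusted p = 0.000143, and adjusted p = 0.307 with an estimated correlation). In MB spheres 14 were lower and 0 higher than in FB, with a median of -0.39 and Fdps at -0.66 (SE 0.05), and the camera adjusted p was 3.33e-07 (adjusted p = 0.00639 with an estimated correlation).

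Circadian clock genes rose in 12 of 14 and fell in 1 between E18 and P70. Dbp rose by a log2 change of 5.23 (SE 0.36), Nr1d1 by 3.26 (SE 0.25) and Bhlhe41 by 3.33 (SE 0.30), while Arntl, which peaks opposite to them in the daily cycle, fell by 0.74 (SE 0.28). The camera adjusted p was 1.36e-07 (adjusted p = 0.00959 with an estimated correlation), and no label gives the hour of collection. Between E13 and E18 clock genes rose in 8 of 13 (camera adjusted p = 0.00209, and adjusted p = 0.119 with an estimated correlation). Arntl was among those that rose there, by 1.05 (SE 0.30). Between E11 and E13 they rose in 2 of 12 (camera adjusted p = 0.159). In MB spheres 11 of 16 were higher and 1, Arntl at -1.42 (SE 0.17), lower than in FB (camera adjusted p = 0.000399, and adjusted p = 0.00639 with an estimated correlation).

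Genes of the Iroquois and Zic families and other dorsal or posterior patterning factors were higher in MB spheres in 7 of 9 and lower in 0, with a median of 3.61. Pax3 differed by 5.25 (SE 0.64), Foxb1 by 4.70 (SE 0.74) and Irx3 by 4.62 (SE 0.74), and the camera adjusted p was 1.05e-05 (adjusted p = 0.00480 with an estimated correlation). Zic1, also on the forebrain list, did not pass (1.02, SE 0.42).

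At E11, 6 heart muscle genes were listed that were not listed at E13. The atrial light chain Myl7 ranged from 4.96 to 190 units over the 4 E11 libraries, and Myl2 from 0 to 31.9. At E18, genes of serotonin neurons ranged widely over the 5 libraries, Tph2 from 0 to 31.7 units, Slc6a4 from 0 to 118 and Fev from 0 to 27.4. Foxj1 ranged from 12.8 to 179 units over the same libraries.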
